A study of Arabidopsis thaliana with 16 samples.

How the data were processed

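Roots of 5-day-old seedlings of 4 Arabidopsis genotypes were analysed from a matrix of gene-level values for 16 libraries, 4 per genotype. Per the labels' protocols, seedlings were grown on plates in long days, total RNA was extracted with Trizol, and libraries were made with a stranded kit for polyadenylated RNA and sequenced on an Illumina instrument. The submitters' processing notes name HISAT2, Cufflinks and the TAIR10 build; versions, parameters and whether the counting used the strand are not given in the sources used here. The values the authors deposited are FPKM, fragments scaled by transcript length and by the mapped fragments of each library, so library size and gene length were already divided out by the authors. No read counts were used, and whole reads could not be recovered, since only a minority of low genes fell on steps of whole fragments. For this reason the tests for counts that were planned for the case of recoverable reads were not run.

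The matrix holds 33560 genes, of which 32826 matched a locus of the TAIR10.1 reference annotation, 26703 of them protein-coding. FPKM below 1e-06 were taken as 0, and 9214 genes were at 0 in all libraries. Each of the 16 columns was matched to 1 library by its name, and 0 columns were left over. Positions and transcript structures are from TAIR10.1, while the authors' build is TAIR10; no coordinates were converted. No pair of libraries held identical values (0 pairs), and log2 values of any pair correlated at 0.981 to 0.995 across genes.

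Depth could be compared only in relative terms. For genes whose FPKM stayed below 0.6, ratios to WT replicate 1 fell on steps of whole fragments within a tolerance of 0.05 on the log2 scale for 22.0 to 39.7% of low genes in the other libraries. The step sizes put the relative depth at 0.88 to 1.61, with means of 1.07 for replicates 1 and 2 and 1.37 for replicates 3 and 4. Absolute depth is unknown, so no counting interval is given. The precision of each value is given by the spread between 4 libraries.

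Genes with an FPKM of at least 1 in at least 4 of the 16 libraries were tested, 19239 in all. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 as 1 mean per genotype over all 16 libraries, with a mean-variance trend and robust moderation of the variances. Tests were 2-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were double, mctp4-1 and mctp3-2 against WT, double against each single mutant, and the interaction, double minus mctp3-2 minus mctp4-1 plus WT. No block entered the fit. A set of 32 gene lists with 438 members was fixed before the data were examined; 11 members whose code carries another gene name in the annotation were dropped and 427 used. Lists with at least 4 measured members were tested with camera from limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 32 lists. Among the lists fixed were markers of root cell types and of green tissue, hormone and nutrient responses, plasmodesmal proteins and clock genes. Members were also adjusted over their list alone. That adjustment does not cover the 32 lists, the comparisons or the fits, so calls over a list alone can arise by chance. With an estimated correlation, the call of the xylem list in double against WT (adjusted p = 0.0113) holds and no other does; with the replicate block that call is lost as well (adjusted p = 0.110). MCTP3 and MCTP4 were also tested by an exact permutation test on log2(FPKM + 1).

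Genes named in the text follow a rule fixed before the data were examined. For each comparison with WT they are MCTP3 and MCTP4, the 10 largest increases and 10 largest decreases among called genes whose 4 mutant libraries all lie on one side of the 4 WT libraries, and up to 4 called members with the smallest adjusted p of each list that was called or had at least 3 called members. For the other comparisons 5 and 5 genes were taken, without the separation of libraries for the interaction. Genes named outside this rule are said to be so, and other list members are given as examples with their values.

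Libraries of different genotypes carry the same replicate numbers in their labels. After subtraction of the genotype means, all 24 pairs of libraries with the same number and different genotypes correlated at 0.203 to 0.556. This is above the limit of 0.1 set beforehand, so the numbers were taken to pair the samples. Pairs of different genotypes with different numbers, within replicates 1 and 2 or within 3 and 4, correlated at 0.185 to 0.524. The limit is thus also met without equal numbers and does not by itself show pairing by number. The pairing comes from the values and the shared numbers, since the labels do not say what a number stands for. The column names of the matrix carry other numbers, the same in every genotype, with a gap between those of replicates 2 and 3. Of the 16 libraries, 14 correlated best with their own number; double replicates 1 and 2 each correlated best with the other's, so the numbers of these libraries may be crossed. They were kept as labelled, and the blocked values for double rest on them; a block of replicates 1 and 2 against 3 and 4, which does not use the numbers within these pairs, was also fitted. The first principal component held 36.7% of the variance and parted replicates 1 and 2 (highest score −18.1) from replicates 3 and 4 (lowest score 19.3), and the second held 9.6%. A fit with the replicate number as a block was made for each comparison, and its values are given beside results whose call it changed or whose count of calls it moved by over 1.5 times.

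The procedure was tested, for double against WT, on simulated data made from the means, replicate differences and spread of the blocked fit to the 19239 genes. The numbers were taken as correct there, so the advantage of the blocked fit was built in and crossed numbers were not simulated. Of 66, 67 and 67 genes changed by 0.5, 1 and 2 on the log2 scale, the fit without a block recovered 36.4, 79.1 and 91.0%, with 0 calls among unchanged genes, and the blocked fit recovered 62.1, 88.1 and 100.0%, with 9 calls among unchanged genes. A list shifted by 0.3 was called in 10 of 10 draws and a list without a shift in 0 of 10. The noise of each gene was drawn independently, so these draws do not test how often lists of genes that vary together are called falsely.

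Alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median of ratios scaling, quantile normalization, only the groups in a contrast, no trend or robust moderation, array quality weights, a log2 change of at least 1, the replicate block, and leaving out each library in turn. Overlaps between comparisons that share the WT libraries were set against 100 simulations of unchanged groups and against 6 splits of the WT libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.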

Results

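Messenger RNA was profiled in roots of 5-day-old Arabidopsis thaliana seedlings of the Col-0 ecotype. The 16 libraries fall into 4 genotypes with 4 libraries each: wild type (WT), the mctp4-1 mutant, the mctp3-2 mutant and the plants carrying both alleles (double). MCTP3 and MCTP4 encode membrane proteins of plasmodesmata, the channels between plant cells, where they tether the endoplasmic reticulum to the plasma membrane. The genotypes allow each allele to be set against wild type, the double to be set against each single mutant, and the double to be set against the sum of the single-mutant changes. The values were FPKM without read counts, so the number of reads behind each value is unknown. FPKM summed to 887430 to 1016221 per library, and 18556 to 18786 genes reached 1 FPKM. Genes not annotated as protein-coding held 4.86, 2.59, 1.62 and 4.22% of the FPKM in WT replicates 1 to 4. They held 1.74, 1.79, 1.19 and 1.42% in those of double and 1.29 to 2.94% in the single mutants. The median log2 change from WT over all genes tested was 0.031 in double, 0.026 in mctp4-1 and 0.049 in mctp3-2. Counts of list members above 0 are to be read against these medians. Steps among the lowest values put the relative depth of the libraries at 0.88 to 1.61 times that of WT replicate 1, with group means of 1.16 for WT, 1.25 for mctp4-1, 1.29 for mctp3-2 and 1.17 for double. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical in part. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

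The mutant loci were examined first. MCTP4 (AT1G51570, chromosome 1, 19122161 to 19125375 on the minus strand of TAIR10.1, 1 transcript with 1 exon) was at 26.3 ± 3.42 FPKM in WT (SD, n = 4), 4.33 ± 1.29 in mctp4-1 and 3.08 ± 0.166 in double. These levels are 16.4% and 11.7% of the WT mean. In mctp3-2 it was at 28.6 ± 1.50 FPKM, 108.4% of WT. MCTP3 (AT3G57880, chromosome 3, 21430922 to 21434648 on the minus strand, 4 transcripts of 2 to 3 exons) was at 6.39 ± 0.236 FPKM in WT (SD, n = 4) and between 5.53 and 8.03 FPKM in the 4 mctp4-1 libraries, with a mean of 6.68. In the libraries labelled mctp3-2 it was higher, at 13.8 ± 1.78 FPKM, and in those labelled double it was at 13.8 ± 0.847, which are 2.16 and 2.15 times the WT mean. A 2-sided exact permutation test of 4 against 4 libraries gave p = 0.0286 for MCTP4 in mctp4-1 and in double and for MCTP3 in mctp3-2 and in double, the smallest p that the 70 arrangements allow. The same exact test gave p = 0.314 for MCTP4 in mctp3-2 and p = 0.714 for MCTP3 in mctp4-1. These exact tests do not use the replicate numbers. For each number MCTP4 was higher in mctp3-2 than in WT, but limma with the replicate number as a block did not call it (adjusted p = 0.816). A transcript level cannot show whether a full-length protein is made, and the FPKM are per gene, so transcript before and after a disrupted site cannot be separated. Because MCTP3 transcript was raised rather than lowered, the directions given for mctp3-2 and double are those of the libraries labelled so.

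**Figure D1:**
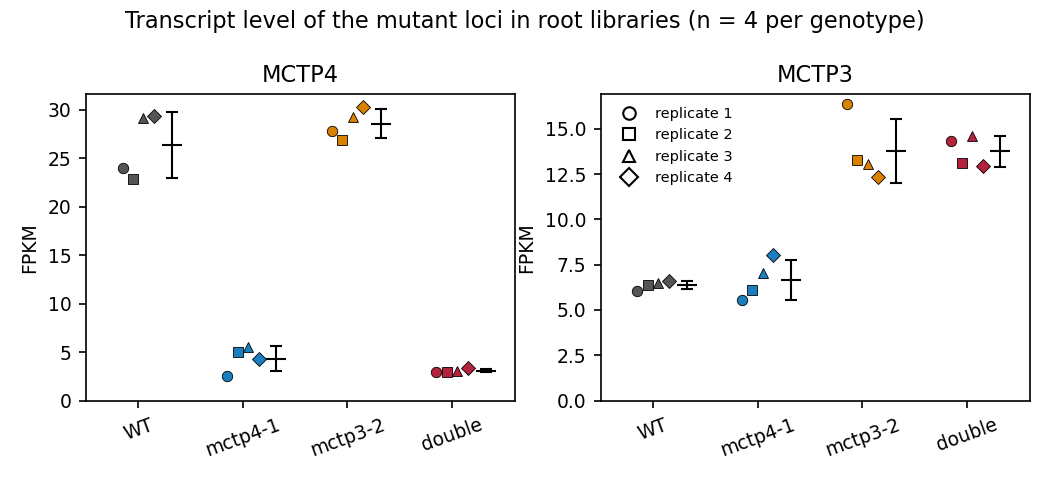
FPKM of MCTP4 and MCTP3 in each of the 16 root libraries, by labelled genotype, with marker shapes for the replicate numbers; horizontal lines are means and error bars are SD (n = 4). MCTP4 lies at 26.3 FPKM in WT and at 4.33 and 3.08 FPKM in mctp4-1 and double, and MCTP3 lies at 6.39 FPKM in WT and at 13.8 FPKM in both groups labelled with mctp3-2.

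In the fit without a block, roots labelled double differed from wild type in 30 of 19239 genes, some strongly changed and 3 of them vascular markers. The replicate block raised the count to 104, and the values here are those without it unless stated. MRD1 (AT1G53480), a gene named for its response in a methionine-accumulating mutant, rose from 0.399 ± 0.330 to 15.1 ± 3.13 FPKM (SD, n = 4; log2 change 3.53 ± 0.23 SE, adjusted p = 4.42e-07). HOL2 (AT2G43920), a methyltransferase gene, rose from 0.331 ± 0.415 to 11.8 ± 3.17 FPKM (log2 change 3.28 ± 0.20 SE, adjusted p = 2.11e-07). AT5G24240, annotated as a phosphatidylinositol kinase of the gamma type, fell from 37.3 ± 4.64 to 1.89 ± 0.476 FPKM (log2 change −3.74 ± 0.16 SE, adjusted p = 2.68e-09). Xylem genes were higher as a group, at a median log2 change of 0.39 over 17 measured members. The list's adjusted p with an estimated correlation was 0.0113, and that call was lost with the replicate number as a block (adjusted p = 0.110 with an estimated correlation).

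Among the other increases, AT1G21520 rose from 0.931 to 8.46 FPKM (log2 change 2.26 ± 0.28 SE) and the transcription factor gene WRKY46 from 0.348 to 4.01 FPKM (1.85 ± 0.24 SE). AT5G03545, a transcript expressed under phosphate starvation, rose from 243 to 266 FPKM in the WT libraries to 456 to 571 FPKM in those of double (n = 4 each; log2 change 1.02 ± 0.10 SE, adjusted p = 3.19e-05). AT5G44400, a berberine-type oxidase gene (1.63), AT3G54530 (1.11), AT3G08490 (0.95) and AT5G51580 (0.84) rose by the log2 changes given. Of a neighbouring pair of genes, the glycosyltransferase gene AT2G41640 rose by 1.31 ± 0.15 SE and AT2G41650 changed by −1.35 ± 0.11 SE, from 344 to 134 FPKM. Their annotated spans overlap by 1144 bp on the same strand, so both values are uncertain where reads could be given to either gene.

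Among the decreases, the hydrolase gene AT2G44970 fell from 26.4 ± 2.37 to 7.32 ± 0.839 FPKM (log2 change −1.72 ± 0.13 SE, adjusted p = 1.48e-06). AT4G08093, a transcribed pseudogene, went from 2.71 to 0.0844 FPKM (log2 change −1.78 ± 0.13 SE), and the retroelement SADHU3-2 went from 12.7 to 3.36 FPKM (−1.66 ± 0.18 SE). The annotation gives both as pseudogenes, and whether they share reads with related copies was not tested, so their levels are uncertain. CYP83A1 (AT4G13770) and MAM1 (AT5G23010), which act in the synthesis of aliphatic glucosinolates, fell by 1.25 and by 0.96 on the log2 scale, with −1.87 and −1.23 in replicates 1 and 2 and −0.64 and −0.69 in replicates 3 and 4. AT1G65370 fell from 20.6 to 9.03 FPKM and AT5G01740 from 14.6 to 6.70 FPKM, the latter with log2 changes of −1.47 in replicates 1 and 2 and −0.55 in replicates 3 and 4. The chitinase family gene AT3G47540 changed by −1.03 ± 0.17 SE.

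In all, limma called 30 genes at a Benjamini-Hochberg adjusted p under 0.05 among 19239 tested, 16 higher and 14 lower, MCTP3 and MCTP4 included. With the replicate number as a block, 104 genes were called, 47 higher and 57 lower, the 30 included. Median of ratios scaling moved the split to 10 higher of 24 called. Without double replicate 3, 18 genes were called. The blocked count was 56 without WT replicate 1, 50 without WT replicate 2, 56 without WT replicate 4 and 159 without double replicate 2. Among the genes called only with the block were AT5G35940 (log2 change 1.61, adjusted p = 1.92e-07), AT3G45160 (−1.02, 2.87e-05) and FSD1 (−0.72, 3.14e-04). These lie outside the rule for named genes and were chosen after their values were seen. Replicates 1 and 2 stood apart from replicates 3 and 4 in all genotypes; 37 genes were called within the former pair and 25 within the latter, and all 30 genes had the same direction in both.

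**Figure D2:**
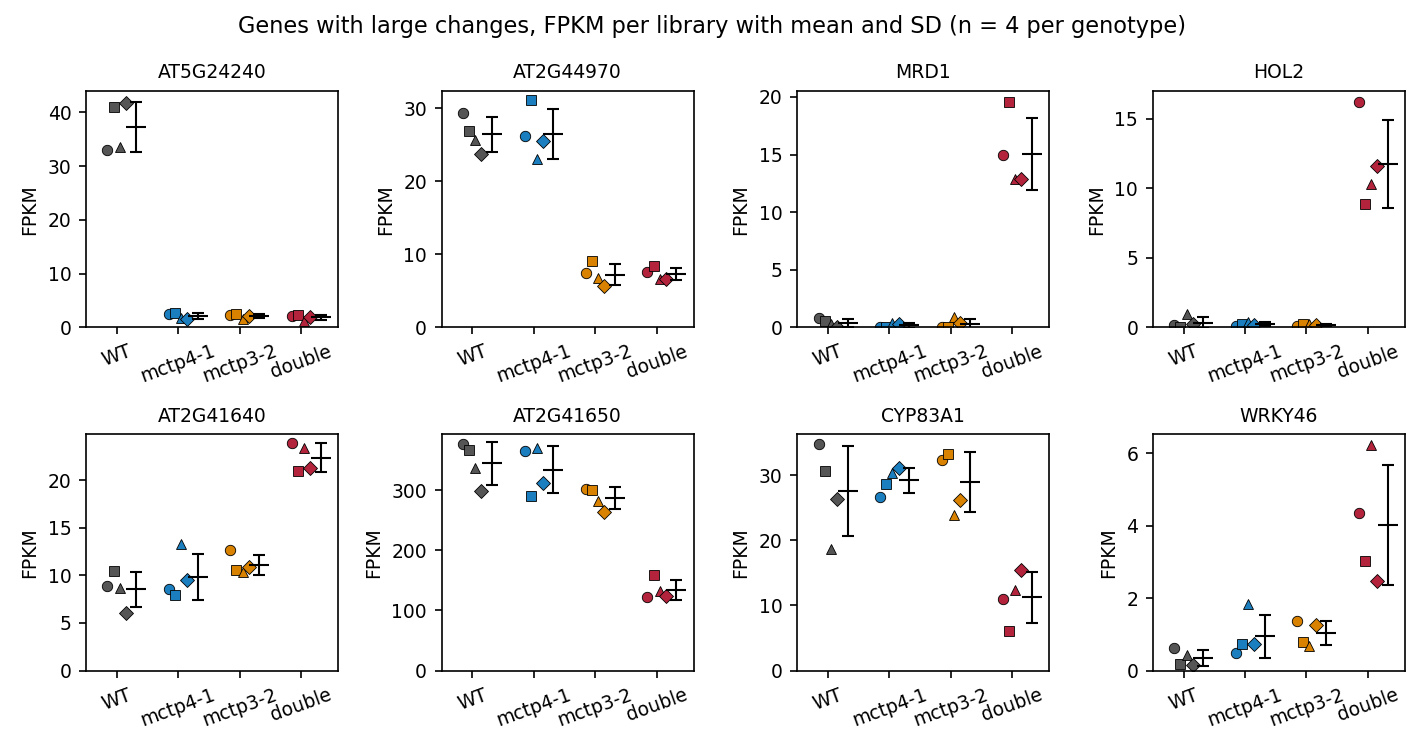
FPKM of 8 genes named in the text in each library of the 4 labelled genotypes; circles, squares, triangles and diamonds are replicates 1, 2, 3 and 4, and horizontal lines with error bars are means and SD (n = 4). MRD1 and HOL2 lie below 1 FPKM on average in WT and in both single mutants and at 15.1 and 11.8 FPKM in double, while AT5G24240 lies at 37.3 FPKM in WT and near 2 FPKM in each mutant genotype.

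Without the replicate block, xylem and phloem markers had the smallest adjusted p of the 32 gene lists set before the data were examined. Of 17 measured xylem and secondary wall markers, 15 lay above 0 in double and 2 were called over all genes: IRX6, a secondary wall gene, at 11.8 ± 0.509 and 17.7 ± 0.949 FPKM in WT and double (log2 change 0.55 ± 0.08 SE, adjusted p = 0.00894), and XCP1, a xylem cysteine peptidase gene, at 121 and 169 FPKM (0.47 ± 0.08 SE, adjusted p = 0.0373). Adjusted over the list alone, 11 of the 17 were higher. With the replicate block IRX9 (0.41, adjusted p = 0.0476) was also called over all genes, and 14 were higher over the list alone. The secondary wall cellulose synthase genes CESA4, CESA7 and CESA8 had log2 values of 0.47, 0.48 and 0.40 and were not called over all genes. The list was called by camera with an adjusted p of 9.11e-19, and with an adjusted p = 0.0113 with an estimated correlation; the replicate block gave 9.30e-15, and an adjusted p = 0.110 with an estimated correlation. All 17 phloem markers lay above 0, with a median log2 change of 0.25 and 1 called, SEOR1 of the sieve elements, which rose from 16.0 to 26.5 FPKM (0.69 ± 0.12 SE, adjusted p = 0.0396). Adjusted over the list alone, 4 phloem markers were higher, and the list's adjusted p was 3.26e-06, with an adjusted p = 0.104 with an estimated correlation.

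**Figure D3:**
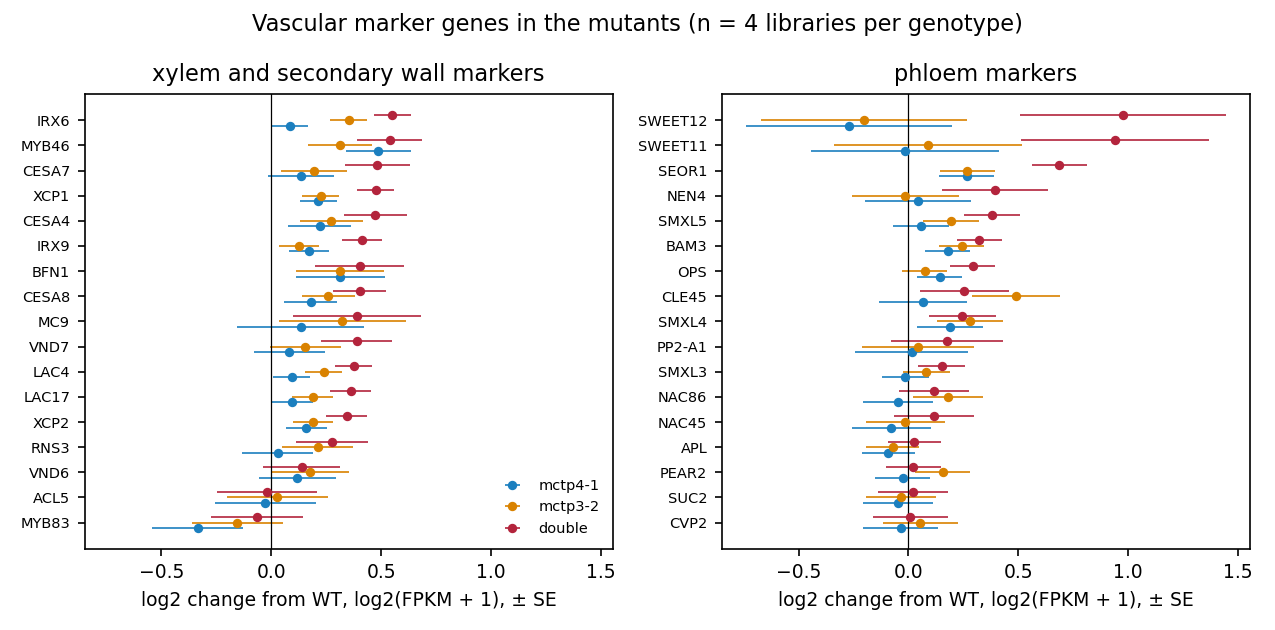
Log2 change from WT of 17 xylem and secondary wall markers and 17 phloem markers in mctp4-1, mctp3-2 and double; points are differences of group means of log2(FPKM + 1) and bars are limma SE (4 libraries per genotype). In double, 15 of 17 xylem markers and 17 of 17 phloem markers lie above 0.

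Another 5 lists were called in double, none of them with an estimated correlation. Auxin response genes were higher (15 of 19 above 0, adjusted p = 0.00583; adjusted p = 0.104 with an estimated correlation), with GH3.1 at 0.60 ± 0.12 SE. Iron deficiency genes were higher (17 of 19 above 0, adjusted p = 0.00483; adjusted p = 0.567 with an estimated correlation), with BHLH38 at 0.78 and IMA1 at 0.97. GH3.1 and BHLH38 were each the 1 member higher when adjusted over the list alone, and with the replicate block both were called over all genes, at adjusted p = 0.0113 and 0.0076. Nitrate response genes were lower (9 of 10 below 0, adjusted p = 7.03e-04; adjusted p = 0.338 with an estimated correlation), with the transporter gene NRT1.1 at −0.44 and the nitrate reductase gene NIA1 at −0.41. Suberin genes were lower (12 of 16 below 0, adjusted p = 0.0289, and 0.825 with an estimated correlation), with CYP86A1 at −0.58 and MYB41 at 0.61. The suberin call held in 17 of 25 alternative settings and was lost under median of ratios scaling and quantile normalization, among others. Photosynthesis genes, markers of green tissue, were lower (17 of 19 below 0, adjusted p = 0.00314; adjusted p = 0.825 with an estimated correlation). The green tissue direction turned between the replicates: the mean log2 change was 0.25 in replicates 1 and 2, with 14 of 19 above 0, and −0.71 in replicates 3 and 4, with 19 of 19 below 0. Without the replicate block no member of the last 3 lists was called, over all genes or adjusted over the list alone. With the block, the nitrate response genes NIA2 (−0.25), NIR1 (−0.31) and LBD38 (−0.21) were lower and MYB41 and the auxin response gene SHY2 (0.39) were higher when adjusted over the list alone. The mean log2 changes in replicates 1 and 2 and in replicates 3 and 4 were 0.11 and 0.22 for auxin response, 0.13 and 0.44 for iron deficiency, −0.25 and −0.13 for nitrate response and −0.09 and −0.18 for suberin.

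The remaining 25 lists were not called in double, with adjusted p from 0.135 for the root stem cell niche to 0.993 for evening genes of the circadian clock. Plasmodesmal proteins (17 members, median log2 change 0.00, adjusted p = 0.421), callose synthases (4 members, 0.319) and proteins of contact sites between endoplasmic reticulum and plasma membrane (6 members, 0.303) were among these, with no member called over all genes. In the MCTP family the 9 measured members besides MCTP3 and MCTP4 were not called, and MCTP2 had the highest value of these, 0.42 ± 0.17 SE. The list adjusted p was 0.887 for salicylic acid response, 0.905 for pattern-triggered immunity, 0.319 for jasmonate response, 0.319 for auxin transport, 0.303 for cytokinin response, 0.748 for gibberellin and 0.905 for brassinosteroid synthesis. It was 0.319 for ethylene, 0.722 for abscisic acid and drought, 0.628 for cell division, 0.445 for root cap markers, 0.454 for root hair cell markers, 0.799 for endodermis and Casparian strip markers and 0.379 for primary wall cellulose. It was 0.714 for the unfolded protein response, 0.421 for heat shock, 0.319 for touch and rapid wounding, 0.202 for phosphate starvation and 0.968 for morning clock genes. The MCTP family list had an adjusted p of 0.866. With the replicate block, PAD3, a camalexin synthesis gene of the immunity list, fell by 0.92 on the log2 scale (adjusted p = 0.00622) and the phosphatase gene PAP17 of the phosphate list rose by 0.70 (adjusted p = 0.0102); without it they were called only when adjusted over the list alone. The block also called higher, over the list alone, WOX5, SCR, SAG101, CALS1, MCTP2, RR5, KIN1, RSL4 and SPX1, at log2 values of 0.29 to 0.53. None of these was called over all genes with the block, at adjusted p from 0.0899 for SPX1 to 0.303 for MCTP2. CASP5 (0.79) and MYB36 (0.27) of the endodermis list were higher over the list alone with and without the block (adjusted p = 0.0322 and 0.0383 for each).

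In mctp4-1, few genes besides MCTP4 differed from wild type. AT5G24240 fell to 2.14 ± 0.556 FPKM (log2 change −3.62 ± 0.16 SE, adjusted p = 4.37e-09), AT4G08093 to 0.0179 FPKM (−1.86 ± 0.13 SE) and SADHU3-2 to 4.06 ± 1.53 FPKM (−1.49 ± 0.18 SE, adjusted p = 0.0027). AT2G13550 fell from 17.3 to 19.4 FPKM in the WT libraries to 8.47 to 11.6 FPKM (n = 4 each; −0.80 ± 0.11 SE, adjusted p = 0.00976), and MCTP4 changed by −2.39 ± 0.15 SE. Limma called these 5 genes and no gene higher, where 242 genes had an unadjusted p under 0.05; the replicate block also called 5, and 3 without WT replicate 2. Within replicates 1 and 2 there were 3 calls and within 3 and 4 there were 2, and the 5 genes were lower in both.

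By camera, 6 lists were called in mctp4-1, and 0 with an estimated correlation. Xylem markers were higher (15 of 17 above 0, median 0.14, adjusted p = 1.93e-04; adjusted p = 0.495 with an estimated correlation), as were auxin response genes (17 of 19, 0.00313; adjusted p = 0.101 with an estimated correlation). Touch and wounding genes (10 of 10 above 0, adjusted p = 0.0283; adjusted p = 0.968 with an estimated correlation) and phosphate starvation genes (15 of 16, 0.0283; adjusted p = 0.495 with an estimated correlation) were higher. The touch list turned between the replicates, with a mean log2 change of −0.12 in replicates 1 and 2 (4 of 10 above 0) and 0.69 in replicates 3 and 4 (10 of 10). Root cap markers (4 of 4 below 0, adjusted p = 0.0283; adjusted p = 0.495 with an estimated correlation) and green tissue markers (16 of 19 below 0, 0.0196; adjusted p = 0.968 with an estimated correlation) were lower. The green tissue list turned as well, with a mean of 0.18 in replicates 1 and 2 (4 of 19 below 0) and −0.48 in replicates 3 and 4 (19 of 19). Its call was also lost under median of ratios scaling and quantile normalization. No single member of these lists was called, over all genes or adjusted over the list alone, except PAP17 (0.50), which was higher over the list alone with the replicate block. The replicate block called 10 lists, adding ethylene (adjusted p = 0.00557), the unfolded protein response (0.00519) and iron deficiency (0.0156) as higher and suberin (0.0344) as lower, with 0.283, 0.705, 0.596 and 0.705 as their adjusted p with an estimated correlation. The mean in replicates 1 and 2 and in replicates 3 and 4 was −0.11 and 0.02 for suberin, −0.16 and −0.08 for root cap markers, 0.07 and 0.15 for the unfolded protein response and 0.10 and 0.21 for iron deficiency. Without WT replicate 4 only 1 list was called and without mctp4-1 replicate 1 there were 2.

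In the libraries labelled mctp3-2, AT5G24240 fell to 2.05 ± 0.405 FPKM (log2 change −3.65 ± 0.16 SE, adjusted p = 3.82e-09) and AT2G44970 to 7.21 ± 1.42 FPKM (−1.75 ± 0.13 SE, adjusted p = 1.73e-06). The pseudogene AT5G35935 went from 4.00 ± 0.579 to 0.0962 ± 0.0384 FPKM (−2.18 ± 0.12 SE, adjusted p = 5.11e-08) and AT4G08093 to 0.0436 FPKM (−1.83 ± 0.13 SE). ALPHA-VPE (AT2G25940), a vacuolar processing enzyme gene, fell from 2.48 ± 0.646 to 0.270 ± 0.164 FPKM (−1.44 ± 0.16 SE, adjusted p = 3.89e-04). MCTP3, at 0.99 ± 0.11 SE, was the 1 gene called higher. Limma called these 6 genes, 5 of them lower. The replicate block called 11, adding SCE1 (0.48) and AT5G35940 (1.77) as higher and AT4G04223 (−1.97), LAF1 (−0.84) and AT5G38005 (−0.84) as lower. These 5 lie outside the rule for named genes and were chosen after their values were seen. There were 4 calls within replicates 1 and 2 and 5 within 3 and 4, and the 6 genes had the same direction in both.

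By camera, 2 lists were called in mctp3-2, and 0 with an estimated correlation. Xylem markers were higher (16 of 17 above 0, median 0.21, 1 member higher when adjusted over the list alone, adjusted p = 6.86e-07; adjusted p = 0.364 with an estimated correlation). Green tissue markers were lower (18 of 19 below 0, median −0.26, adjusted p = 2.53e-06; adjusted p = 0.817 with an estimated correlation), with a mean of −0.12 in replicates 1 and 2 and −0.45 in replicates 3 and 4. The replicate block called 4 lists, adding the unfolded protein response as higher (adjusted p = 0.00449; adjusted p = 0.759 with an estimated correlation) and nitrate response as lower (0.0285; adjusted p = 0.692 with an estimated correlation). It also called SAG101 (0.49) and BR6OX1 (0.35) higher when adjusted over the list alone. There were 4 lists without WT replicate 1, 4 without mctp3-2 replicate 2 and 6 without mctp3-2 replicate 4.

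The genes called in double were set against those called in each single mutant. MCTP4, SADHU3-2, AT4G08093 and AT5G24240 were lower in double and in mctp4-1. AT2G44970, AT4G08093, AT5G24240 and AT5G35935 were lower and MCTP3 was higher in double and in mctp3-2. MCTP3 and MCTP4 are the mutant loci, whose alleles double has in common with the singles, so their sharing follows from the design. The pattern of AT4G08093 and AT5G24240, lower in all 3 mutant genotypes, could also come from the wild-type stock. Apart from these, SADHU3-2 was shared with mctp4-1, and AT2G44970 and AT5G35935 with mctp3-2. Since all 3 comparisons use the same WT libraries, 100 simulations of unchanged groups against 1 shared simulated WT group were run, and they gave 0 shared calls. All 16 libraries were simulated there without effects, so this count does not show what the real WT libraries contribute. Independent lists of these sizes would share 0.00364 lower genes with mctp4-1 and 0.00364 lower and 8.32e-04 higher genes with mctp3-2; neither value includes both the effects and the shared controls. With the WT libraries split between the comparisons, 3 to 4 genes were shared with mctp4-1 and 4 to 5 with mctp3-2. With the replicate block, 8 genes were shared with mctp3-2, against 0.00733 higher and 0.0237 lower for independent lists.

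Over all 19239 genes, the covariance of log2 changes was 0.0184 for double and mctp4-1, where unchanged groups gave 0.0146 (0.0114 to 0.0208), a difference of 0.00376. For double and mctp3-2 it was 0.0190 against 0.0148 (0.0116 to 0.0211), a difference of 0.00420. Both observed values lie within the simulated range. The correlations across genes, which are not independent replicates, were 0.527 and 0.508, against 0.497 and 0.499 simulated. With the WT libraries split, the covariances ranged from −0.0386 to 0.00653 and from −0.0350 to 0.00675 over 6 splits. The 6 splits were also made with only the mutant libraries that carry the same numbers as the WT libraries on each side. The covariances then averaged 0.00523 and 0.00564, with ranges of −0.00533 to 0.0117 and −0.00219 to 0.0147, which include 0.

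Double was next set against each single mutant. MRD1 (3.78 ± 0.23 SE against mctp4-1 and 3.64 ± 0.23 SE against mctp3-2), HOL2 (3.36 and 3.39, each ± 0.20 SE) and AT1G21520 (1.86 and 2.00, each ± 0.28 SE) rose against both. CYP83A1 (−1.36 and −1.34) fell against both, and so did AT2G41650, from 334 and 287 FPKM in the single mutants to 134 FPKM. Against mctp4-1, AT2G41640 (1.13), AT5G03545 (0.58) and MCTP3 (0.95) rose and AT2G44970 (−1.72), MAM1 (−1.09) and ALPHA-VPE (−0.94) fell. Against mctp3-2, the noncoding RNA AT4G04223 rose from 5.05 ± 1.58 to 38.4 ± 24.4 FPKM (2.54 ± 0.33 SE, adjusted p = 0.00322), AT5G35935 rose from 0.0962 to 1.72 FPKM, and MCTP4 (−2.86) and SADHU3-2 (−1.18) fell. Limma called 12 genes against mctp4-1, 6 higher and 6 lower, and 11 against mctp3-2, 7 higher and 4 lower. The replicate block called 60, 20 of them higher, and 53, 21 of them higher. Without mctp4-1 replicate 1 or without mctp4-1 replicate 4 the first count was 7, and without mctp3-2 replicate 2 the second was 7. Within replicates 1 and 2 there were 9 and 10 calls, and within 3 and 4 there were 9 and 7.

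Xylem markers were also higher in double than in either single mutant (17 of 17 above 0 against mctp4-1, adjusted p = 1.90e-12; 15 of 17 against mctp3-2, 4.07e-08), with adjusted p = 0.0559 and 0.228 with an estimated correlation. Phloem markers were higher against both (17 of 17, adjusted p = 2.47e-07; 12 of 17, 9.42e-04), with adjusted p = 0.0943 and 0.377 with an estimated correlation. Against mctp3-2 the phloem mean was 0.08 in replicates 1 and 2, with 8 of 17 above 0, and 0.31 in replicates 3 and 4, with 15 of 17. Nitrate response genes were lower than in mctp4-1 (10 of 10 below 0, adjusted p = 1.57e-04; adjusted p = 0.316 with an estimated correlation). Against mctp3-2, the lists of iron deficiency (0.00336), endodermis and Casparian strip (0.00886) and auxin response (0.048) were higher and suberin (0.0109) was lower, with 0.568, 0.602, 0.377 and 0.888 as their adjusted p with an estimated correlation. These changes were uneven between the replicates. In replicates 1 and 2 and in replicates 3 and 4 the mean was 0.27 (9 of 9 above 0) and 0.00 (4 of 9) for the endodermis, 0.06 (9 of 19) and 0.32 (17 of 19) for iron deficiency, −0.02 (8 of 19) and 0.16 (17 of 19) for auxin response, −0.12 and −0.35 for suberin and 0.11 and 0.19 for xylem. The replicate block added cytokinin response (0.018) and root hair cell markers (0.018) as higher against mctp3-2, with 0.578 and 0.827 as their adjusted p with an estimated correlation. With the block IRX6 (0.47) was called against mctp4-1 over all genes (adjusted p = 0.00957) and PAD3 was lower against both (−0.80 and −0.96; adjusted p = 0.0231 and 0.00786). Adjusted over the list alone, it raised the xylem members higher against mctp4-1 from 3 to 6 and the suberin members lower against mctp3-2 from 0 to 7. Over the list alone it also called PDLP4, a plasmodesmal protein gene, lower against both (−0.59 and −0.75) and F6'H1 lower against mctp4-1 (−0.41). KIN1 (0.36) and PAP17 (0.45) were higher against mctp3-2 in the same way. None of these was called over all genes with the block (adjusted p 0.0727 to 0.216). PHO1;H1 of the phosphate list was lower against mctp3-2 over the list alone with and without the block (−0.46, adjusted p = 0.0052 and 0.00809).

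The interaction contrast asked whether double departed from the sum of the single-mutant changes on the log2 scale. MRD1 (3.88 ± 0.33 SE, adjusted p = 2.20e-05) and HOL2 (3.47 ± 0.28 SE, adjusted p = 2.04e-05) lay above the sum, with FPKM below 1 on average in WT and both single mutants. AT2G41650 lay below it (−1.05 ± 0.15 SE, adjusted p = 0.0103), a call lost with median of ratios scaling. AT5G24240 (3.53 ± 0.22 SE) and AT4G08093 (1.92 ± 0.18 SE) were also called, but their sums, −7.27 and −3.69, lie below 0 FPKM from WT levels of 5.25 and 1.89 on the log2 scale. No level of double could have reached these sums, so the test says nothing of them; in both genes, the double differed from each single mutant by less than 1 SE. AT4G04223 (3.65 ± 0.46 SE, adjusted p = 0.00355) was at 22.4 FPKM in WT, 9.87 in mctp4-1, 5.05 in mctp3-2 and 38.4 in double. AT5G35935 (1.28 ± 0.17 SE, adjusted p = 0.00355) was named outside the rule for named genes, after its value was seen. Limma called these 7 genes, and the replicate block called 10, adding FSD1 (−0.92) and AT3G45160 (−0.82) below the sum and AT5G38005 (1.22) above it, also named after their values were seen. The sums of the other 5 genes called without the block stay above 0 FPKM. Within replicates 1 and 2 there were 2 calls, within 3 and 4 there were 2, and the 7 genes had the same direction in both. With a pseudocount of 0.1 MRD1 was not called (adjusted p = 0.0848).

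No list was called in the interaction by camera, the smallest adjusted p being 0.0786, for phloem and for green tissue markers, so the xylem and phloem changes of double were not shown to depart from the sum of the single mutants. The replicate block called 1 list, the unfolded protein response, lower (11 of 11 members below 0, adjusted p = 0.00775; adjusted p = 0.910 with an estimated correlation), and PDLP4 (−0.80) and PAD3 (−0.84) lower when adjusted over the list alone. PHO1;H1 (−0.55) was lower over the list alone with and without the block (adjusted p = 0.022 and 0.0329). Leaving out WT replicate 3 or 4, mctp4-1 replicate 1 or 3, or double replicate 2 gave 1 list, mctp3-2 replicate 1 or double replicate 1 or 3 gave 2, mctp4-1 replicate 2 or mctp3-2 replicate 2 gave 3, and double replicate 4 gave 4.

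Calls close to the threshold were the least stable. In double against WT, those of CYP83A1, MAM1, SEOR1, XCP1, AT3G08490, AT3G54530, AT5G01740, AT5G44400 and AT5G51580 (adjusted p 0.0373 to 0.0441) were each lost in 13 to 18 of 26 or 27 alternative settings, most of them with 1 library left out, and kept their direction in all. Against the single mutants, the call of CYP83A1 was lost in 14 of 27 settings for mctp3-2 and in 8 of 27 for mctp4-1. Against mctp4-1, those of MAM1 and AT5G03545 were each lost in 10 of 27, ALPHA-VPE in 11 of 26 and AT1G21520 in 7 of 26, and against mctp3-2 that of SADHU3-2 in 7 of 27, with the direction kept.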

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

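Of the tests that weigh an explanation and the counts over other splits, only the one with green tissue markers as a covariate was set down before its result was seen; the others were chosen after.

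AT5G24240 and AT4G08093 were lower in all 3 mutant genotypes, to levels that did not part the double from the singles. Linkage to a mutant locus is argued against, since 0 of the 2 genes lie on the chromosome of MCTP3 or MCTP4. A response to lower MCTP4 transcript is argued against, since MCTP4 stood at 0.119 (log2) against WT in mctp3-2, where both genes were lower. A seed stock of the wild type that differs from the mutant lines at these genes could give the pattern: the largest difference of the double from a single mutant was −0.75 SE. With 1 wild-type line in the design, that explanation and an effect common to all mutants cannot be told apart.

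MCTP3 transcript was higher, not lower, in the libraries labelled mctp3-2 and double. A swap of single libraries is argued against, since 0 of 16 had MCTP3 or MCTP4 on the side of another label, and so is a rise in answer to lower MCTP4, since MCTP3 stood at 0.044 in mctp4-1. An exchange of the labels of whole groups stays open: with WT and mctp3-2, and mctp4-1 and double, exchanged, MCTP3 would change by −0.99 in mctp3-2 and MCTP4 would still follow its labels, so the 2 cases cannot be told apart. A candidate explanation is that the mctp3-2 lesion changes transcription around it: SCE1, the gene next to MCTP3, stood at 0.48 in mctp3-2 and 0.44 in double (adjusted p = 0.0034 and 0.00273 with the replicate block, 0.334 and 0.137 without), while other neighbours stood at 0.17 or less and were not called. Whether the raised transcript encodes a whole protein stays open, since the FPKM are per gene.

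Xylem and secondary wall markers were higher in double, by 0.35 ± 0.06 SE on average with the replicate block. A rise shared with suberin genes is argued against, since their upper 95% bound was 0.056 and the lower bound for xylem genes 0.204. Suberin genes were the only marker of mature root used in this test. The endodermis and Casparian strip list lay at 0.067 (95% bounds −0.157 to 0.291), which reaches past the xylem bound, so a larger share of mature root stays open. Less green tissue in the sample is argued against as the whole cause, since the change was 0.33 ± 0.07 SE with the green markers as a covariate, and so is the scaling of the libraries, with adjusted p of 3.16e-19 or smaller under median of ratios scaling and quantile normalization. Only 1 of 35 splits, the real one, gave as small a p for the list (2.85e-20, smallest other 1.62e-12). The list was followed over the splits after its small p in the real grouping had been seen. The smallest p over all lists was not compared between splits, so this share does not exclude chance. The 8 splits that part all pairs (2.91e-16 with the replicate block, smallest other 1.21e-09) are too few for a share under 0.05. With the block and an estimated correlation the list was not called (adjusted p = 0.110). In mctp4-1, 3 of 35 splits, the real one included, gave as small a camera p for this list (6.03e-06, smallest other 1.11e-08). In mctp3-2, 1 of 35 did (2.14e-08, smallest other 7.38e-08). An effect of the genotype on xylem genes may be involved, and a difference in growth stage within the vascular tissue was not tested.

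In 160 groups of 4 libraries tested for a single library far from the other 3, 5 had one, where chance alone gives about 1 in 20. AT3G08490 was at 3.95 FPKM in WT replicate 2, with the others at 2.54 to 2.67, and at 3.13 FPKM in mctp4-1 replicate 3, with the others at 4.18 to 4.38. IRX6 was at 19.1 FPKM in double replicate 2, with the others at 17.1 to 17.4. AT5G35935 was at 1.301 FPKM in double replicate 1, with the others at 1.85 to 1.87, and AT4G04223 was at 6.98 FPKM in mctp4-1 replicate 3, with the others at 10.5 to 11.1.

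The effect of the double differed from the sum of the single mutants, by the interaction test, for 7 genes: MRD1 (3.88), AT4G04223 (3.65), AT5G24240 (3.53), HOL2 (3.47), AT4G08093 (1.92), AT5G35935 (1.28) and AT2G41650 (−1.05). The labels name no further line of any genotype. A difference private to the double line and an effect of both alleles together thus cannot be told apart. For AT5G24240 and AT4G08093 the sum lies below 0 FPKM, so the floor of the scale fixed the sign of the difference and the test is void for them. Of 100 assignments of the labels, 1 gave as many as 7 genes, the real one, and the highest other count was 3. Over genes whose sum stays at or above 0 FPKM the real count was 5, given by 1 of the 100, and the highest other 1. These assignments ignore the pairs and stand for no effect of any genotype, not for single-mutant changes that add up. They therefore do not exclude chance for an interaction count. For lists in the interaction the real count was 0, so all 100 assignments gave as many, up to 13.

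Among the 35 splits of 8 libraries, only the real one gave as many genes as double against mctp4-1 (12, highest other 1). The same held for double against mctp3-2 (11, highest other 1). The split of replicates 1 and 2 against 3 and 4 called 0 genes in both, although 8551 genes were called between these replicates over all 16 libraries. A low count in another split can thus hide real differences, so these shares do not exclude chance. Among the 8 splits that part all pairs the highest others were 1 and 0, and with the replicate block the counts were 60 and 53 and the highest others 1 and 1; 8 splits are too few for a share under 0.05. For double, mctp4-1 and mctp3-2 against WT, 2 of 35 splits gave as many genes as the real 30, 5 and 6. The other one in each case parted replicates 1 and 2 from 3 and 4, with 3983, 3312 and 1685 genes, so it follows a structure of the libraries that is not genotype, and a share of 2 in 35 does not exclude chance. Among the 8 splits that part all pairs of equal number, the highest other count was 0 in each of these 3 comparisons. With the replicate block the real counts were 104, 5 and 11 and the highest others 0, 1 and 0, each real count being given by 1 of 8 splits, again too few for such a share. For lists called, chance is not excluded: 18 of 35 splits gave as many as the 7 in double (highest other 13), 16 of 35 as many as the 6 in mctp4-1 (highest other 12) and 31 of 35 as many as the 2 in mctp3-2 (highest other 10). With the replicate block and the 8 splits that part all pairs, the real counts of lists were 7, 10 and 4 in double, mctp4-1 and mctp3-2 and the highest others 10, 5 and 7; 8 splits are too few for a share under 0.05.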

How the results depend on the processing

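The block of replicates 1 and 2 against 3 and 4, the counts and list means within each of these pairs, the count without genes whose sum lies below 0 FPKM, the blocked fits with other scalings or with a library left out, and the alternatives for shared calls were chosen after the data were seen. No called result reversed under the settings below. Within replicates 1 and 2 the green tissue means in double and mctp4-1 had the opposite sign to those within 3 and 4. So had those of the touch and suberin lists in mctp4-1, auxin response in double against mctp3-2 and the sulfur list in double. Of 68 results for named genes, 1574 of 1805 alternatives kept the call or the lack of one, and 231 kept the direction without the call. Results that were not called did not always keep their direction. MCTP3 in double against mctp3-2, never called, ranged from −0.043 to 0.083. A mean FPKM of at least 5, which tests fewer genes, gave 3 genes for mctp3-2 against WT, 7 for double against mctp4-1, 7 against mctp3-2, 3 for the interaction and 3 shared by double and mctp3-2. Fitting only the groups in the contrast, with fewer libraries, gave 14 for double and 3 for mctp4-1 against WT and 7 for double against mctp3-2. A log2 change of at least 1 left 18 for double against WT, and array quality weights gave 23 for double against mctp4-1; the cause was not tested. The replicate block, which removes the difference between replicate numbers, gave 104 genes for double and 11 for mctp3-2 against WT, 60 and 53 for double against mctp4-1 and mctp3-2 and 8 shared by double and mctp3-2, and 10 lists for mctp4-1, 4 for mctp3-2 and 1 for the interaction; it ended no call made without it, except those of the xylem list in double and of the aliphatic glucosinolate list in the interaction with an estimated correlation. A block of replicates 1 and 2 against 3 and 4 gave 101, 58, 59 and 12 for double against WT, mctp4-1 and mctp3-2 and the interaction; under it the xylem list in double had an adjusted p = 0.0661 with an estimated correlation. With an estimated correlation 1 list was called in double, 0 in mctp4-1 and 0 in mctp3-2. No filter gave 3 lists for mctp4-1 and 1 for the interaction, and a mean FPKM of at least 5 gave 4 for mctp3-2 and 1 for the interaction. Leaving out 1 library at a time gave 18 to 28 genes for double against WT (50 to 159 with the block), 4 to 5 for mctp4-1 (3 to 6), 6 to 7 for mctp3-2 (9 to 12), 7 to 14 and 7 to 13 for double against mctp4-1 and mctp3-2, 7 in every case for the interaction, 4 shared with mctp4-1 and 5 to 6 with mctp3-2. Lists ranged over 5 to 8 in double, 1 to 7 in mctp4-1, 2 to 6 in mctp3-2 and 0 to 4 in the interaction. The tests for counts were not run, since read counts were not recovered, and the unknown depth leaves the precision of genes below 1 FPKM open.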

Other observations

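The glucosinolate lists and the comparison of replicates 1 and 2 with 3 and 4 were chosen after the called genes and the first principal component had been seen. Genes of aliphatic glucosinolate synthesis, to which CYP83A1 and MAM1 belong, were lower in double as a group: 17 of 18 measured members lay below 0, with a median log2 change of −0.82. The mean change was −1.12 in replicates 1 and 2, with 18 of 18 below 0, and −0.37 in replicates 3 and 4, with 16 of 18 below 0. BCAT4, which starts the chain elongation of methionine, was at 37.2 ± 18.9 FPKM in WT and 11.5 ± 2.35 in double (SD, n = 4; −1.48), the isopropylmalate dehydrogenase gene IMD1 at 97.3 ± 28.8 and 47.5 ± 6.21 (−0.98), and the regulator gene MYB28 at 30.1 ± 9.72 and 19.9 ± 3.98 (−0.54). Over all genes 2 members were called, 13 when adjusted over the list alone, and 9 and 16 with the replicate block. The list's adjusted p by camera was 7.41e-28, with an adjusted p = 0.00585 with an estimated correlation, but the list was written after 2 of its members had been called, so it is no independent evidence. In mctp4-1 and mctp3-2 the medians were 0.04 and 0.04 and the list was not called (adjusted p = 0.875 and 0.465). The interaction gave 18 of 18 members below 0 (adjusted p = 5.43e-19; adjusted p = 0.022 with an estimated correlation, and 0.055 with the replicate block and an estimated correlation), with 6 members lower over the list alone and 13 with the block. The median in double ranged from −1.05 to −0.61 with 1 library left out. Of 35 splits of the 8 libraries, 1 gave a p as small as the real 2.47e-28, and the next smallest was 6.19e-25, so other splits came close.

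Lists of indole glucosinolate synthesis (median −0.23, 10 of 11 members below 0, adjusted p = 0.00808) and of sulfur limitation (median −0.19, 5 of 9 below 0, adjusted p = 0.00984) were lower in double, with adjusted p = 0.0888 and 0.224 with an estimated correlation. With the replicate block the indole list was called at an estimated correlation (adjusted p = 0.0148) and the sulfur list was not (adjusted p = 0.207). GSTF9, in the former, was the 1 member called over all genes with the block (−0.50, adjusted p = 0.0106), with 6 members lower over the list alone; without it no member was called either way. The mean of the sulfur list was −0.51 in replicates 1 and 2 and 0.06 in replicates 3 and 4, so its direction turned.

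Replicates 3 and 4 differed from replicates 1 and 2 in every genotype. Limma called 8551 genes between them, 5364 higher and 3187 lower in replicates 3 and 4. The mean log2 level of the morning clock genes, replicates 3 and 4 minus 1 and 2, differed by −1.87 in WT, −1.82 in mctp4-1, −1.98 in mctp3-2 and −1.84 in double, and that of the evening clock genes differed by 1.57, 1.44, 1.40 and 1.26. Green tissue markers differed by −0.18, −0.85, −0.52 and −1.15. The labels give no time of harvest.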
